A study of Mus musculus with 18 samples.

How the data were processed

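RNA from C2C12 myotubes, muscle fibre-like cells grown from a mouse myoblast line, was measured on Illumina mouse whole-genome bead arrays. The cultures had received dexamethasone (Dex, a synthetic glucocorticoid) at 1 uM or ethanol at 0.01% of the medium volume, in medium with 2% horse serum, for 6 h or 24 h. The labels list 18 arrays in 4 groups, 4 ethanol and 4 Dex arrays at 6 h and 5 of each at 24 h, and each sample was placed in its group by its own title. The design text speaks of triplicates, while the labels number the samples of a group up to 4 or 5, so all numbered samples were used. It also states that the arrays of all treatments came from a single batch. No label says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

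The deposited values are linear probe intensities, made by the authors with the lumi package, per the submitters' processing notes. The version of lumi, the background correction and the normalization method are not given in the sources used here. The design text also names limma for the authors' own tests, whose output was not used here. The array medians lay between 99.8 and 100.4 at 6 h and between 85.2 and 86.8 at 24 h, and the array minima between 70.4 and 70.8 at 6 h and between 60.4 and 61.2 at 24 h. Values were therefore treated as comparable within a time, while a comparison across times seems to cross 2 normalizations, which the sources used here do not state. Scanner files, detection p-values, chip numbers and dates were not used here, so it is unknown which probes lay above background, and the fold change of a dim gene is understated by the background left in its value. The design had been written for log2 values. Since the deposited intensities were linear, log2 of the intensity was taken with a pseudocount of 0.

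Of the 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none. Symbols were updated through the gene identifier to the annotation of assembly GRCm38.p6 for 34807 probes and kept for 78. No coordinates were used. Each gene was represented by its brightest probe by mean log2 value over the 18 arrays, which gave 19057 genes. Of the named genes called at 6 h, 24 had several probes, and all probes were called the same way for 10 of them. At 24 h these numbers were 26 and 10. In these 2 comparisons no probe of a named gene was called in the opposite direction. One linear model with a mean for each of the 4 groups was fitted over the 18 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3. Dex was compared with ethanol at 6 h and at 24 h, the Dex effects at the 2 times were compared with each other (the interaction), and ethanol at 24 h was compared with ethanol at 6 h. P-values were adjusted by the Benjamini-Hochberg method over the 19057 genes of a comparison, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes come from the model, and intensities are given as mean ± SD over the arrays of a group.

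A set of 20 gene lists was tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, with adjustment over the 20 lists. Camera asks whether a list moved further than the other genes. The gene lists, the tests, the alternatives and the rule for the genes named in the text were fixed before the data were examined. The rule took, per comparison, the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap (for the interaction, among called genes). For each list with at least 3 called members in a Dex comparison it took the 2 members with the smallest p, or 4 if camera called the list. It always took Fkbp5, Tsc22d3, Per1, Klf15, Fbxo32, Trim63, Pik3r1, Mstn and Nr3c1. A few further list members are named below as examples and were chosen after their values were seen.

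The model was tested on simulated arrays with 19057 genes. For the 6 h comparison it recovered 28%, 94%, 98% and 100% of 50 genes changed by 0.25, 0.5, 1 and 2 on the log2 scale. For the 24 h comparison it recovered 54%, 96%, 98% and 100%. Unchanged genes made up 6.43% of the calls at 6 h and 6.95% at 24 h in these simulations. The changed genes were drawn from the brighter genes only, so recovery of dim genes was not tested. The simulated arrays kept all directions of spread. Their spread was taken over more residual degrees of freedom than the values hold, as described next, so recovery may be overstated.

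Deviations from the group means spread over fewer directions than the arrays allow. With 8 arrays in 2 groups at 6 h, 6 directions are possible, and the smallest held 2.08e-05% of the spread of the 786 genes with a mean log2 value above 12. At 24 h, 8 directions are possible, and the smallest 3 held 0.000293%, 0.000107% and 2.42e-05%. In simulated untouched arrays the smallest 3 of 8 directions together held 32.6% of the spread. The model therefore counts 14 residual degrees of freedom where the values hold 10. In simulated arrays with no change and with such directions taken out, 9.80% of genes had an unadjusted p under 0.05 in the 6 h comparison and 10.2% in the 24 h comparison, while 0 and 6 of 19057 genes were called after adjustment. With the missing directions entered as covariates the unadjusted shares were 4.98% and 5.37%, and no gene was called in either comparison. This return follows by construction, since the directions entered were those taken out, so it does not test the covariates on the deposited values. The simulated genes were also independent of each other, so false calls among correlated genes were not tested. The values hold fewer residual degrees of freedom than the model counts. The counts of genes called in each comparison and at both times are therefore given also with the 4 missing directions as covariates. This alternative was chosen after seeing the data. The results without the covariates are the ones fixed in advance.

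The alternatives set beforehand were quantile normalization and median centring over all arrays, leaving out the genes below the median or below the lower quartile of mean log2 value, the mean of a gene's probes, tests per probe, eBayes with trend and robust settings, array weights, the replicate number as a block, an adjusted p under 0.01, a change of at least 1.5-fold, leaving out each array in turn, and fits on the 2 compared groups alone. Added after seeing the data were the covariates, normexp background correction with an offset of 50, leaving out both arrays numbered 1 at 24 h, and the extension of some of these settings to lists, overlaps and named genes. The number of arrays limits the precision of all values.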

Results

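The series measured mRNA levels in C2C12 myotubes after 6 h and 24 h with Dex or with its vehicle ethanol. According to its title it concerns target genes of the glucocorticoid receptor, the nuclear receptor that Dex binds. Within a group, the correlation across genes between 2 arrays was at least 0.993 in each of the 4 groups, and no pair of arrays held the same values, the smallest SD of a log2 difference within a group being 0.101. Genes are not independent replicates, so these correlations describe the arrays only. Intensities near 100 at 6 h or near 86 at 24 h lie at the array median.

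After 6 h with Dex, the largest rises were in Serpina3n, a serine protease inhibitor secreted in the acute-phase response, Angptl7, a secreted angiopoietin-like protein, Fkbp5, a co-chaperone of the glucocorticoid receptor, Mt2, a metal-binding metallothionein, Plin4, a lipid droplet coat protein, and Edn1, the precursor of the vasoconstrictor endothelin-1. Serpina3n went from an intensity of 107 ± 5.78 (SD, n = 4) with ethanol to 2312 ± 114 (SD, n = 4) with Dex, a log2 fold change of 4.43 (SE 0.13, limma adjusted p = 2.06e-17). Fkbp5 went from 274 ± 21.0 to 4180 ± 229, a log2 fold change of 3.93 (SE 0.07). Angptl7 rose by 4.05, Mt2 by 3.37, Plin4 by 3.12 and Edn1 by 2.58 on the log2 scale. The largest falls were in Ch25h, the cholesterol 25-hydroxylase, with a log2 fold change of -2.26 (SE 0.11, limma adjusted p = 4.34e-13), in G0s2, an inhibitor of triglyceride lipase (-1.83), in the chemokine Cxcl12 (-1.68), in the transcription factor Egr2 (-1.55), in the small GTPase Rerg (-1.34) and in the metalloproteinase inhibitor Timp3 (-1.31).

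In all, 1726 of 19057 genes were called at 6 h, 890 higher and 836 lower with Dex, and 253 of them changed at least 1.5-fold. The groups did not overlap for 2077 of the 19057 genes, 1305 of them called. Chance would separate 2.86% of genes in this way if the arrays were exchangeable. The missing directions shrink the spread within groups, so the share by chance is likely higher here. With the missing directions as covariates 850 genes were called, 472 higher and 378 lower, all of them among the 1726. The 8 arrays of this time fitted alone gave 908 calls, and array weights gave 1079.

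Of 26 classical glucocorticoid receptor targets, 16 rose and 1 fell at 6 h, or 17 and 2 adjusted over the list alone (camera adjusted p = 4.33e-23, and adjusted p = 4.41e-06 with an estimated correlation). The kinase gene Sgk1 rose by 1.71 on the log2 scale, from 4044 ± 151 to 13220 ± 524 (SD, n = 4 each), Tsc22d3, which encodes the anti-inflammatory protein GILZ, rose by 1.69 and the clock gene Per1 by 1.27. The called member that fell was Angptl4, an inhibitor of lipoprotein lipase, at -0.89 (SE 0.12). The probes of Klf15 and of Nr3c1, the receptor gene itself, read 105 ± 2.66 and 107 ± 9.96 with ethanol, close to the array median, and neither gene passed the test (Klf15 0.05, adjusted p = 0.729; Nr3c1 -0.02, adjusted p = 0.904).

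Among 21 muscle atrophy and FoxO genes, 6 rose and 1 fell at 6 h, the same numbers as adjusted over the list alone (camera adjusted p = 0.00271, and adjusted p = 0.0169 with an estimated correlation). The deubiquitinase gene Usp2 rose by 1.16, the muscle ubiquitin ligase genes Trim63 (MuRF1) and Fbxo32 (atrogin-1) by 0.93 (SE 0.13) and 0.60 (SE 0.09), and the ubiquitin ligase gene Cblb by 0.80. The mean of a gene's probes gave 0.45 for Usp2 and 0.27 for Cblb. The myostatin gene Mstn read 83.4 ± 4.19 with ethanol and 79.7 ± 4.53 with Dex (adjusted p = 0.576). Of 32 genes of insulin, PI3K and mTOR signalling, 7 rose and 1 fell, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0239, and adjusted p = 0.0357 with an estimated correlation). This call was lost with the mean of a gene's probes (adjusted p = 0.0911), without the genes below the median intensity (0.0926) and without ethanol replicate 4 (0.0514). The members that rose included the mTORC1 inhibitors Ddit4 (1.84) and Sesn1 (1.32), the insulin receptor substrate Irs2 (0.84), Mtor itself (0.54) and the PI3K regulatory subunit Pik3r1 (0.52, SE 0.10). With the mean of a gene's probes Mtor had 0.21 and Pik3r1 0.25.

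Of 18 measured genes of cholesterol synthesis, none rose and 10 fell at 6 h, or 15 adjusted over the list alone, with a median log2 fold change of -0.31 (camera adjusted p = 3.05e-11, and adjusted p = 0.0284 with an estimated correlation). Insig1, a sterol-regulated brake on this pathway, had a log2 fold change of -0.93 (SE 0.13), the sterol carrier gene Stard4 -0.54, the sterol demethylase gene Cyp51 -0.54 and Fdps, the farnesyl diphosphate synthase, -0.38. With the missing directions as covariates 4 members were called lower and the list kept its call. Of 31 inflammatory cytokines and NF-kB targets, 4 rose and 7 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.0202 downward, but adjusted p = 0.0641 with an estimated correlation and 0.103 with the mean of a gene's probes). Beside Cxcl12, the adhesion molecule Vcam1 fell by 1.07, the chemokine Ccl7 by 1.05 and the transcription factor Irf1 by 0.70. The mean of a gene's probes gave -0.70 for Cxcl12, -0.28 for Vcam1 and -0.39 for Irf1, and the other 3 probes of Vcam1 were not called. The rises included Nfkbia, the NF-kB inhibitor, at 0.76. Of 35 genes of oxidative phosphorylation, 6 fell and none rose, also adjusted over the list alone (4 fell with the missing directions as covariates), among them Ndufb9 (-0.61), Sdhd (-0.40), Ndufb5 (-0.31) and Ndufs8 (-0.26). Camera's adjusted p was 0.0434, but adjusted p = 0.712 with an estimated correlation, and the call was also lost without ethanol replicate 2 (0.198), ethanol replicate 4 (0.0514), Dex replicate 1 (0.437) or Dex replicate 3 (0.0870), without the genes below the median intensity (0.0934) and with normexp (0.0528). The call of Sdhd was lost without ethanol replicate 4 or with array weights.

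The other 14 lists did not pass camera's threshold at 6 h, with adjusted p from 0.291 upward, although single members did. Of 34 collagen and matrix genes, 7 rose and 5 fell, or 9 and 7 adjusted over the list alone, led by the matricellular Ccn2 (1.87) and the metalloproteinase Adamts1 (0.84). The list's median of -0.01 and its mean of 0.09 differed in sign. Of 29 fatty acid oxidation and PPAR genes, 2 rose and 6 fell, and Pdk4, the kinase that inhibits pyruvate dehydrogenase, rose by 1.78. Of 18 clock genes, 3 rose and 4 fell, with Per2 at 0.64. Of 24 myogenic regulators, 3 rose and 3 fell, with Myf6 at 0.85 and the Notch target Hes1 at -0.69. Of 42 sarcomere genes, 1 rose and 3 fell, with the myosin light chain Myl2 at -1.07 and the tropomyosin Tpm1 at -0.62. Of 30 cell cycle genes, 2 rose and 2 fell, with Rrm2 at 0.51 and Tyms at -0.32. Of 35 ribosomal protein genes, 1 rose and 3 fell, with Rps3 at -0.28 and Rps7 at -0.22. The calls of Tyms, Rps3 and Rps7 were lost with the missing directions as covariates (adjusted p = 0.0575, 0.0901 and 0.160). The rises and falls were 0 and 2 of 31 for proteasome subunits, 0 and 2 of 26 for interferon-stimulated genes, 1 and 1 of 27 for glycolysis, 1 and 1 of 23 for amino acid response genes, 0 and 0 of 26 for autophagy genes, 0 and 1 of 13 for adipocyte-like markers, and 1 and 1 of 10 for osteoblast-like markers. Adjusted over the list alone, the rises and falls were 4 and 6 for fatty acid genes, 3 and 5 for clock genes, 4 and 4 for myogenic regulators, 2 and 4 for cell cycle genes and 2 and 2 for osteoblast-like markers, and as above for the other 9 lists. Median, mean and camera's direction also differed in sign for the glycolysis, sarcomere, clock and osteoblast-like lists.

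After 24 h with Dex, Serpina3n was again the gene with the largest rise. It went from 77.9 ± 5.85 to 4715 ± 1188 (SD, n = 5 each), a log2 fold change of 5.88 (SE 0.11, limma adjusted p = 2.76e-21). Orm1, which encodes the acute-phase protein orosomucoid, followed at 4.27 (SE 0.08), from 80.8 ± 4.15 to 1573 ± 283, then Angptl7 at 3.42, Fkbp5 at 3.40 (SE 0.07), Amy2a5, an amylase gene, at 3.34 and Edn1 at 3.11. The rise of Amy2a5 rests on 1 of its 3 probes, since the other 2 were not called (-0.04 and 0.12), and the mean of its probes gave 1.14. Serpina3n, Orm1 and Angptl7 read below the array median with ethanol and are not shown to be above background there, so their fold changes and ranks describe intensities and understate the change if background is part of these readings. The largest falls were in Fgf21, a secreted metabolic hormone, at -2.29 (SE 0.35), Ch25h at -2.25 (SE 0.10), the small proline-rich gene Sprr2k at -2.13, the matrix protein gene Spon2 at -1.88, the glutamate transporter gene Slc1a3 at -1.80 and Trib3, a stress-induced pseudokinase gene, at -1.79 (SE 0.28). In Fgf21 the arrays of a group differed widely, with 3756 ± 1985 in ethanol and 759 ± 369 in Dex (SD, n = 5 each, limma adjusted p = 4.67e-05).

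At 24 h 3142 of 19057 genes were called, 1598 higher and 1544 lower, and 313 of them changed at least 1.5-fold. The groups did not overlap for 3103 of the 19057 genes, 2257 of them called. Chance would give 0.794% of genes with exchangeable arrays, and likely more here because of the missing directions. With the missing directions as covariates 1694 were called, 852 higher and 842 lower, all of them among the 3142. Array weights gave 5552 calls.

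Of the 26 classical receptor targets, 19 rose and 2 fell at 24 h, or 19 and 3 adjusted over the list alone (camera adjusted p = 7.92e-18, and adjusted p = 2.13e-05 with an estimated correlation). Errfi1, an inhibitor of the EGF receptor, rose by 1.76, Sgk1 by 1.54, Tsc22d3 by 1.43 and Per1 by 1.35, while Angptl4 had a log2 fold change of -1.33. Klf15 (0.04, adjusted p = 0.724), Mstn (-0.08, adjusted p = 0.322) and Nr3c1 (-0.14, adjusted p = 0.163) did not pass the test, though Nr3c1 did without both arrays numbered 1. Of the 21 atrophy and FoxO genes, 8 rose and 2 fell, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.0157, and adjusted p = 0.0410 with an estimated correlation). Fbxo32 rose by 1.14 (SE 0.08), from 490 ± 54.8 to 1084 ± 153 (SD, n = 5 each), Usp2 by 1.05, Bcat2, a branched-chain aminotransferase gene, by 0.53 and Trim63 by 0.47 (SE 0.11), and the TWEAK receptor gene Tnfrsf12a fell by 0.54. Of the 32 insulin, PI3K and mTOR genes, 9 rose and 4 fell, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0157, and adjusted p = 0.0410 with an estimated correlation). Ddit4 rose by 1.56, Sesn1 by 1.46, Irs2 by 0.93, the mTOR-binding inhibitor gene Deptor by 0.78 and Pik3r1 by 0.72 (SE 0.09).

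Of 23 genes of the amino acid response, which the transcription factor ATF4 drives, 1 rose and 18 fell at 24 h, or 1 and 20 adjusted over the list alone, with a median log2 fold change of -0.52. Camera's adjusted p was 1.26e-10, but adjusted p = 0.133 with an estimated correlation, which was 0.451 between the genes of this list. Trib3 fell by 1.79, the folate cycle enzyme gene Mthfd2 by 1.44 (SE 0.23), Chac1, a glutathione-degrading enzyme gene, by 1.41 and the asparagine synthetase gene Asns by 1.13. The member that rose was Vldlr, a lipoprotein receptor gene, by 1.20. The list's mean log2 level, taken relative to the 18 arrays, ranged from -0.21 to 0.46 over the 5 ethanol arrays and from -0.85 to -0.23 over the 5 Dex arrays at 24 h. Its highest ethanol array and its lowest Dex array both carried the replicate number 1, and without both of them 13 members were called lower and the median was -0.32. Over all genes the deviations of these 2 arrays from their group means correlated at -0.928, so the 2 extremes cannot be read as separate observations.

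Of the 31 inflammatory genes, 4 rose and 10 fell at 24 h, or 5 and 11 adjusted over the list alone (camera adjusted p = 0.0157 downward, but adjusted p = 0.0790 with an estimated correlation). Cxcl12 fell by 1.58 (-0.80 with the mean of its probes), Vcam1 by 1.32 (-0.38 with the mean of its probes) and the chemokine Ccl2 by 0.54, while the acute-phase gene Saa3 rose by 1.60. Of 35 ribosomal protein genes, 7 rose and 2 fell, or 8 and 2 adjusted over the list alone, with Rps19 at 0.23, Rps6 at 0.22, Rpl19 at 0.18 and Rpl4 at -0.26. Camera's adjusted p was 0.0404, but adjusted p = 0.721 with an estimated correlation. The call was also lost with quantile normalization (0.0790), with the missing directions as covariates (0.0505) and without any of 5 single arrays, which were ethanol replicates 2, 3 and 4 and Dex replicates 2 and 5 (at most 0.0873). With these covariates Rps19, Rps6 and Rpl19 were not called either (adjusted p = 0.0775, 0.0830 and 0.0991). The mean of a gene's probes, array weights and normexp ended the list's call as well (0.0632, 0.0574 and 0.0594).

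The other 14 lists did not pass camera's threshold at 24 h. Among 34 collagen and matrix genes, 9 rose and 15 fell, or 9 and 17 adjusted over the list alone (camera adjusted p = 0.165). The basement membrane collagens Col4a2 and Col4a1 rose by 1.98 and 1.88, while the fibrillar collagen Col1a1 had a log2 fold change of -0.56, the proteoglycan Lum -1.09 and Col8a1 -1.30. Of 18 cholesterol synthesis genes, 1 rose and 2 fell, with Mvk at 0.21 and Cyp51 at -0.27. Of 24 myogenic regulators, 4 rose and 7 fell, with Myf6 at 0.61 and the growth factor Igf2 at 0.57. Of 42 sarcomere genes, 7 rose and 3 fell, with Mybpc1 at 0.94 and the calcium-binding Casq2 at 0.48. Of 29 fatty acid genes, 6 rose and 4 fell, and of 27 glycolysis genes 4 rose and 1 fell, with Pdk4, a member of both lists, at 2.29 and the phosphofructokinase Pfkp at -0.48. Of 35 oxidative phosphorylation genes, 4 rose and 1 fell, with Sdhc at 0.31 and Uqcrc2 at 0.25. Of 30 cell cycle genes, 3 rose and 4 fell, with Cdk1 at 0.43 and Mcm6 at -0.31. Of 26 autophagy genes, 3 rose and 3 fell, with Gabarapl1 at 0.30 and Atg5 at -0.18. The calls of Cyp51 and Atg5 were lost with the missing directions as covariates (adjusted p = 0.0533 and 0.0849), and those of Cdk1, Mcm6, Rps19 and Atg5 with the mean of a gene's probes. Without both arrays numbered 1, Atg5 and Rpl4 were not called. Of 18 clock genes, 2 rose and 2 fell, with Arntl at -0.33. The counts were 0 and 1 of 31 for proteasome subunits, 0 and 2 of 26 for interferon-stimulated genes, and 0 and 1 of 10 for osteoblast-like markers. Of 13 adipocyte-like markers, 3 rose and none fell, with Cebpa at 0.44 and Dgat2 at 0.40 (camera adjusted p = 0.0803). Adjusted over the list alone, the rises and falls were 6 and 7 for myogenic regulators, 9 and 5 for sarcomere, 5 and 1 for glycolysis, 6 and 3 for oxidative phosphorylation, 3 and 5 for cell cycle, 4 and 6 for autophagy and 0 and 0 for proteasome genes, and as above for the other 6 lists. Median, mean and camera's direction differed in sign for the autophagy, interferon, sarcomere, cell cycle and osteoblast-like lists.

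**Figure D1:**
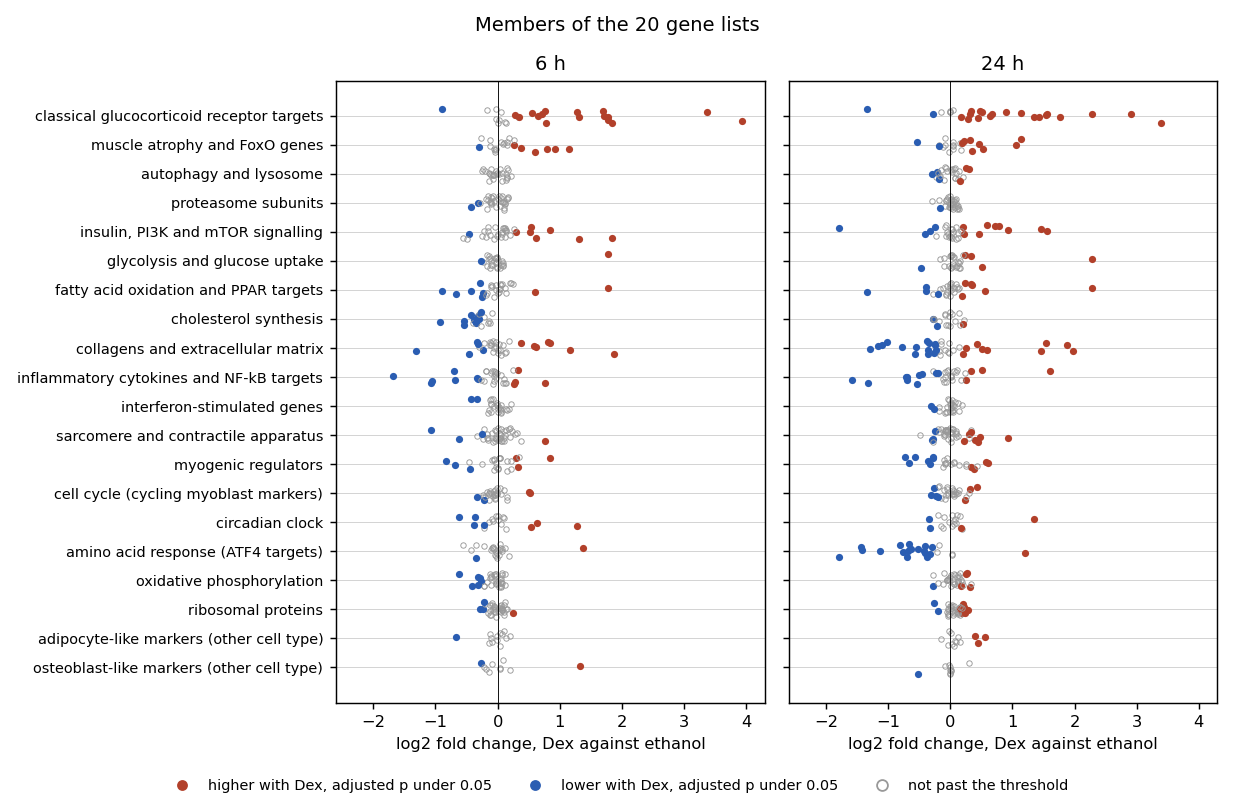
Log2 fold changes of the members of the 20 gene lists with Dex against ethanol at 6 h (left) and 24 h (right), 1 point per gene, filled where the adjusted p was under 0.05 (red higher, blue lower). The 10 called cholesterol synthesis genes at 6 h and 18 of the 19 called amino acid response genes at 24 h lie below 0.

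Many genes responded at both times. Of the genes called at 6 h, 426 were higher and 287 lower at 24 h too, against 74.6 and 67.7 if the calls at the 2 times were independent (Fisher's exact test, p = 1.34e-231 and p = 4.45e-110, 2-sided). Genes are not independent replicates, so these p-values describe the overlap only. Fkbp5, Serpina3n, Edn1, Cxcl12 and Ch25h are among these genes. A further 63 genes were called in opposite directions, and with the missing directions as covariates 10 of them. The lipase gene Lpl, for example, had a log2 fold change of -0.67 at 6 h and 0.56 at 24 h, and the Notch target Hey1 -0.44 and 0.38. Across the 19057 genes the fold changes at the 2 times had a Pearson r of 0.561 and a Spearman rho of 0.237. The 2 comparisons share no arrays, but their calls rest on a common estimate of the spread per gene. A gene with a small spread is thus more easily called at both times, so the calls are not independent. With the arrays of each time fitted alone, 545 genes were called at both times in the same direction. With the missing directions as covariates 427 genes were called at both times in the same direction, against 713 without.

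**Figure D2:**
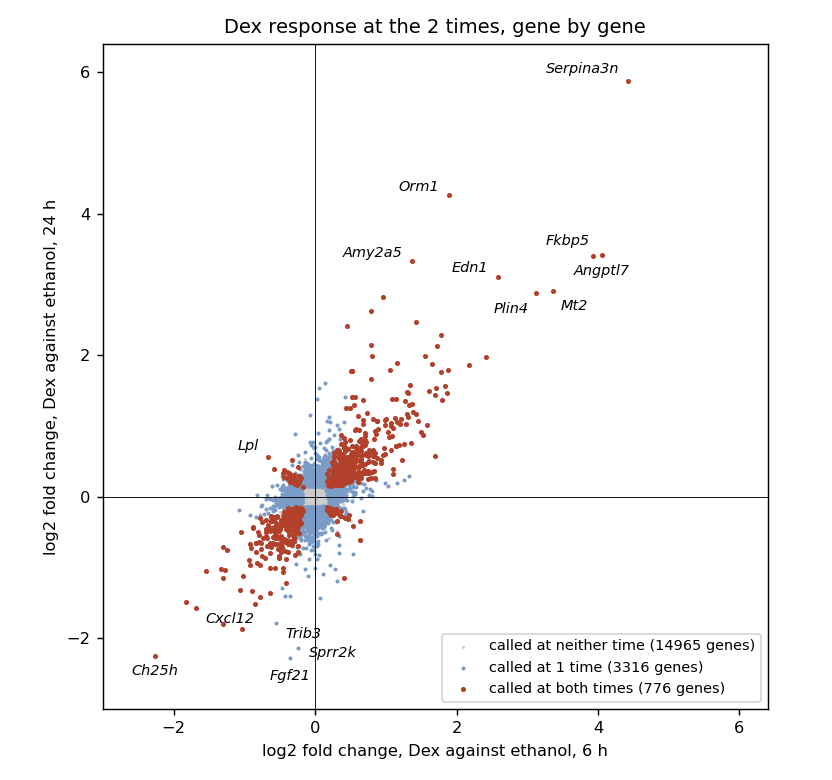
Log2 fold change with Dex against ethanol at 6 h (horizontal axis) and at 24 h (vertical axis) for 19057 genes, 1 point per gene, coloured by the number of times at which it was called. Serpina3n lies at 4.43 and 5.88, Ch25h at -2.26 and -2.25, and Lpl in the quadrant of opposite changes.

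The Dex effects at the 2 times were compared gene by gene. The effect on Orm1 was larger at 24 h by 2.38 on the log2 scale (SE 0.13, limma adjusted p = 3.54e-11, with ethanol readings below the array median at both times, so the size is that of the intensities), that on Amy2a5 by 1.97 (0.64 with the mean of its probes), that on 4930486L24Rik by 1.95, that on Lbp, the lipopolysaccharide-binding protein gene, by 1.85, that on the plasma glutathione peroxidase gene Gpx3 by 1.84 and that on the thrombospondin gene Thbs2 by 1.48. For Gpx3 the ethanol arrays read 1103 ± 248 (SD, n = 4) at 6 h and 158 ± 10.7 (SD, n = 5) at 24 h, against 1885 ± 299 and 983 ± 168 with Dex. The effect was lower at 24 h for Fgf21 (-1.94, SE 0.52), Sprr2k (-1.90), the retinol dehydrogenase gene Rdh5 (-1.56, or -0.81 with the mean of its probes), Mthfd2 (-1.51, SE 0.35), Serpinb9g (-1.49) and Ntn5 (-1.35). The calls of Fgf21 and Ntn5 were lost with the missing directions as covariates (adjusted p = 0.0763 and 0.0720), and those of Fgf21, Mthfd2 and Ntn5 with the trend and robust settings of eBayes (0.111, 0.0599 and 0.0981). Those of Fgf21 and Ntn5 were also lost with the mean of a gene's probes and without both 24 h arrays numbered 1. The call of Fgf21 was lost too without any 1 of 9 arrays (ethanol 3 and 4 and Dex 1, 2 and 3 at 6 h, ethanol 1 and 2 and Dex 1 and 4 at 24 h). That of Ntn5 was lost without any 1 of 8 (ethanol 3 and 4 and Dex 1 and 2 at 6 h, ethanol 1, 2 and 5 and Dex 1 at 24 h).

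The Dex effects differed in 942 genes, 469 in the upward and 473 in the downward direction, and in 232 with the missing directions as covariates, all of them among the 942. Of the 2366 genes called only at 24 h, 474 passed this test, and of the 950 called only at 6 h, 257 passed. All 63 genes called in opposite directions passed, and 66 of the 713 called in the same direction at both times.

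Among the gene lists, the Dex effect was lower at 24 h for the amino acid response genes (7 of 23 called lower, median difference -0.56, camera adjusted p = 4.29e-08, but adjusted p = 0.433 with an estimated correlation). It was higher at 24 h for cholesterol synthesis (5 of 18 called higher, median 0.29, camera adjusted p = 3.44e-07, but adjusted p = 0.282 with an estimated correlation), with Stard4 at 0.70 and Insig1 at 0.66. It was also higher for oxidative phosphorylation (6 of 35, camera adjusted p = 0.000883, but adjusted p = 0.442 with an estimated correlation), with Ndufb9 at 0.77. Glycolysis (1 higher and 1 lower of 27), ribosomal proteins (2 higher and 1 lower of 35) and collagens (3 higher and 7 lower of 34) had camera adjusted p-values of 0.0210, 0.0336 and 0.0362, and with an estimated correlation adjusted p = 0.442, 0.588 and 0.547. Each of these 3 calls was also lost without ethanol replicate 4 at 24 h (0.0538 in each case), and the calls of ribosomal proteins and collagens without 5 further arrays each, at most at 0.179 and 0.340. Adjusted over the list alone, 14 amino acid response genes were lower, 9 cholesterol and 8 oxidative phosphorylation genes higher, 3 collagen genes higher and 11 lower, and 5 glycolysis genes higher and 1 lower. The 6 lists kept camera's call with the missing directions as covariates, but the called members fell to 2 lower for the amino acid response, 1 higher for cholesterol synthesis, 3 higher for oxidative phosphorylation and 3 higher and 3 lower for collagens, with 1 lower left for glycolysis and for ribosomal proteins. The other 14 lists did not pass, with camera adjusted p from 0.0593 for the adipocyte-like markers upward. No difference was shown for the receptor targets (2 of 26 lower, adjusted p = 0.333) or the atrophy genes (1 higher and 1 lower of 21, adjusted p = 0.686), in which the difference was 0.54 for Fbxo32 and -0.45 for Cblb. Median, mean and camera's direction differed in sign for the autophagy, insulin, inflammatory and interferon lists.

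**Figure D3:**
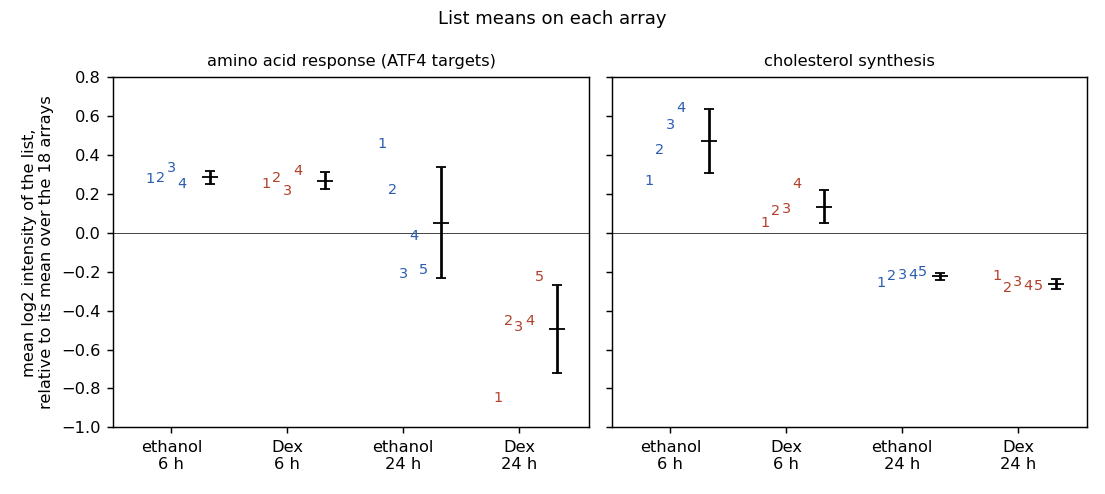
Mean log2 intensity of the amino acid response list (left) and the cholesterol synthesis list (right) on each array, relative to the list's mean over the 18 arrays, with arrays shown by their replicate numbers and the mean ± SD of each group (n = 4 at 6 h, n = 5 at 24 h). The ethanol and Dex arrays numbered 1 at 24 h sit at 0.46 and -0.85 in the left panel.

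In ethanol cultures, levels at 24 h were set against those at 6 h, across arrays whose medians and minima point to separate normalization of the 2 times. As deposited, the median gene was lower at 24 h by a log2 change of -0.26, and 14741 of the 15037 called genes were lower and 296 higher (13340 and 237 with the missing directions as covariates). After quantile normalization of all arrays together 5748 genes were called, 2799 higher and 2949 lower, after median centring 6394, 1356 higher and 5038 lower, and after normexp background correction 8561, 478 higher and 8083 lower. The direction of most genes thus rests on the scaling, and the named genes are given under both scalings. The membrane protein gene Fxyd6 had a log2 change of -2.88 (SE 0.18) as deposited and -2.39 after quantile normalization, Gpx3 -2.78 and -2.35, the integrin gene Itga11 -2.49 and -2.08, Ndrg4 -2.39 and -1.93, Myl2 -2.25 and -1.76, and the DNA ligase gene Lig1 -2.25 and -1.80. The dynactin gene Dctn1 rose by 1.83 (SE 0.10) as deposited and by 2.17 after quantile normalization, Eif4b by 1.00 and 1.45, Magea2 by 0.91 and 1.27, Magea8 by 0.90 and 1.20, Mgst1 by 0.89 and 1.35, and Plac8 by 0.83 and 1.17. With the mean of a gene's probes Lig1 had -0.74 as deposited, its other 3 probes lying between -0.29 and -0.14, and Itga11 had -1.40. For Eif4b and Magea2 the rise rests on the brightest probe, since the other probe of each was called lower as deposited (-0.65 and -0.36), and the mean of a gene's probes gave 0.17 and 0.28. The other probe of Magea8 was not called (-0.10), and the mean of its probes gave 0.40.

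The lists too depend on the scaling. Of 34 collagen and matrix genes, 2 were higher and 31 lower in ethanol at 24 h as deposited, and 2 higher and 17 lower after quantile normalization (camera adjusted p = 8.31e-05 after it, but adjusted p = 0.371 with an estimated correlation). The ribosomal protein genes turned, with 5 of 35 higher and 16 lower as deposited (median -0.16) and 16 higher and none lower after quantile normalization (median 0.18, camera adjusted p = 2.39e-05, but adjusted p = 0.371 with an estimated correlation), so only their shift relative to the other genes held. Of 18 cholesterol synthesis genes, 17 were lower as deposited and 10 after quantile normalization (0.0135), of 30 cell cycle genes 26 and 11 (0.0164) and of 42 sarcomere genes 35 and 16 (0.0164). With an estimated correlation these 3 lists had adjusted p = 0.372, 0.371 and 0.556. The other 15 lists were not called after quantile normalization.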

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

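The tests of the patterns weighed here were chosen after the result was seen, except the test of separate normalization for the amino acid response list and the counts over other splits of the arrays without covariates.

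The Dex effect differed between 24 h and 6 h, by the test of the interaction, for 36 of the 104 genes named by the rule. Over all genes it differed for 942 of 19057. The rule drew 12 of the 36 from genes already called in this test, so their passing was fixed beforehand and the 2 shares cannot be compared. It was higher at 24 h, in log2 units, for Orm1 (2.38), Amy2a5 (1.97), 4930486L24Rik (1.95), Lbp (1.85), Gpx3 (1.84), Thbs2 (1.48), Saa3 (1.46), Serpina3n (1.45), Col4a2 (1.17), Ndufb9 (0.77), Mybpc1 (0.74), Col4a1 (0.73), Stard4 (0.70), Sdhd (0.67), Insig1 (0.66), Casq2 (0.63), Fbxo32 (0.54), Egr2 (0.49), Cdk1 (0.49), Ndufb5 (0.44), Rps3 (0.40), Fdps (0.34) and Mvk (0.29). It was lower at 24 h for Fgf21 (-1.94), Sprr2k (-1.90), Rdh5 (-1.56), Mthfd2 (-1.51), Serpinb9g (-1.49), Ntn5 (-1.35), Per2 (-0.66), Adamts1 (-0.58), Fkbp5 (-0.53), Rpl4 (-0.50), Pfkp (-0.47), Cblb (-0.45) and Mtor (-0.41). The lists whose effects differed were the amino acid response genes (adjusted p = 4.29e-08), cholesterol synthesis (3.44e-07), oxidative phosphorylation (0.000883), glycolysis (0.0210), ribosomal proteins (0.0336) and collagens (0.0362), none of them called with an estimated correlation.

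In 7 of 222 groups of arrays tested for the named genes, 1 array stood apart from the others of its group, where chance gives about 11.1. The gap to the nearest array, as a share of the group's range, was 0.954 for Ndufb9 in Dex replicate 4 at 6 h (1073 against 872), 0.898 for Edn1 in ethanol replicate 3 at 6 h (126 against 147), 0.862 for Vcam1 in ethanol replicate 4 at 6 h (954 against 1302) and 0.839 for Cdk1 in Dex replicate 2 at 24 h (621 against 491). It was 0.751 for Slc1a3 in ethanol replicate 1 at 24 h (924 against 547), 0.725 for Mstn in the same array (70.1 against 73) and 0.713 for Vcam1 in ethanol replicate 3 at 24 h (935 against 959).

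Among the 10378 probes with no gene name, which no comparison above used, 429 passed the threshold with Dex at 6 h (191 higher, 238 lower) and 984 at 24 h (562 higher, 422 lower). These are 4.13% and 9.48% of such probes, against 6.90% and 13.6% of the named probes.

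Fewer directions of spread than the arrays allow point to a dependence between arrays in the deposited values. An array copied from a few others would leave the remaining arrays with weights near 0 in the missing direction at 6 h, but the smallest weight was 0.215 in size. Cultures that respond more strongly to Dex would show deviations along the Dex fold changes, but the largest correlation across genes at 24 h was 0.131 in size. It ran over all genes, 13109 of them with a mean log2 value of at most 8. Noise in these may hold it down, so a varying response is not excluded. A candidate explanation that stays open is that components shared by same-numbered arrays were removed: at 24 h the 3 missing directions lay along the replicate numbers better than under any other of the 120 ways to match the numbers (a share of 0.00833), although only by 94.7% against 94.2%. At 6 h, 1 other of the 24 ways did better (98.9% against 97.3%), so the numbers are a less clear guide there.

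The fall of the amino acid response genes at 24 h is larger on the arrays numbered 1, but these do not carry it alone, since without both the median log2 fold change was -0.32 with camera's adjusted p at 1.38e-08, and adjusted p = 0.132 with an estimated correlation. The median difference of the Dex effects was -0.56 as deposited and -0.57 after quantile normalization of all arrays together. Each Dex effect is taken within a time, where a shift common to all arrays of that time cancels. Quantile normalization could therefore hardly move this median, and the test does not decide on separate normalization. A rise of these genes in ethanol cultures that Dex prevented may contribute and cannot be told apart from a fall under Dex, because after quantile normalization the median change from 6 h to 24 h was 0.23 in ethanol and -0.35 in Dex, and the ethanol change rests on scaling across times. A biological effect of Dex on the ATF4 pathway is a hypothesis that these values leave open.

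Of the genes called in the ethanol comparison 1.97% were higher at 24 h as deposited and 48.7% after quantile normalization of all arrays. Separate normalization of the 2 times may produce this skew, but it cannot be told apart from a true fall of most levels with time in culture, because quantile normalization forces equal distributions and so removes either. A change with time stays open and was not tested.

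In other splits of the arrays, 1 split, the real one, gave as many genes in each case, but the directions missing around the real groups favour the real split. The splits were therefore counted again with these directions as covariates in every split, and again 1 split, the real one, gave as many. For Dex at 24 h, with 100 of 126 splits drawn, the real split then gave 1694 genes and the highest of the other splits 574, and for ethanol across the times 13577 and 11252. The directions were taken around the real groups. As covariates they can absorb part of the contrast of another split but none of the real one. This recount can therefore still favour the real split, and it does not exclude chance for the Dex count at 24 h. If the numbers pair the arrays at 24 h, only 16 splits exchange arrays within pairs, too few for a share under 0.05, so chance stays open. For ethanol, the different array medians of the 2 times set the real split apart beforehand, so the splits cannot decide there. Without the covariates the values were 3142 and 498, and 15037 and 11202. For Dex at 6 h, with 35 splits in all, the real one included, the real split gave 850 genes and the highest of the others 410 with the covariates, and 1726 and 895 without. The split with 895 genes set the arrays numbered 1 and 2 against those numbered 3 and 4. The split with 410 genes set ethanol 1, 3 and 4 and Dex 4 against the other arrays, so it did not follow the numbers. A structure along the numbers cannot be read from the highest split alone. If the numbers pair the arrays at 6 h, which depends on the genes looked at, only 8 splits exchange arrays within pairs, too few for a share under 0.05. For the interaction, the real split gave 942 genes and the highest of the other splits 0, or 232 and 20 with the covariates. Whether chance can be excluded for this count is left open, because the Dex arrays of a time share the error of the ethanol mean subtracted from them, and this favours the real split.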

How the results depend on the processing

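The fits with the missing directions as covariates, with normexp and without both 24 h arrays numbered 1 were chosen after the result was seen, as were some settings of the lists, the overlap and the named genes. No named gene and no list that was called in either of 2 compared settings reversed direction, a list being judged by camera's direction relative to the other genes. For ethanol across the times, though, the levels of lists turned with quantile normalization: the median went from -0.16 to 0.18 for ribosomal, from -0.24 to 0.06 for inflammatory and from -0.21 to 0.23 for amino acid response genes, and other lists also moved upward. Of the named genes that were not called, Nr3c1 at 6 h (-0.08 to 0.03) and Klf15 at 24 h (at most 0.08) changed sign with single arrays left out. Within 1.5 times the reported count stayed 36 of 58 counts under the alternatives and all 45 with 1 array left out (6 h 1238 to 1827, 24 h 2370 to 2756, interaction 633 to 1033, ethanol 14212 to 14674), and for the overlap 11 of 14 and 18 of 18. Of 920 list results 857 kept their side of the threshold, 52 lost and 11 gained a call. Most of the 920 concern lists that were not called in the reported fit and so had no call to lose. Camera with an estimated correlation ended most of the list calls, among them all those in the interaction and in the ethanol comparison. Of 1551 values of named genes 1516 did, 34 lost and 1 gained a call. Without both 24 h arrays numbered 1, 2520 genes were called at 24 h, 704 in the interaction and 637 at both times. The cause was not tested for any change below except where genes, arrays or thresholds differ by construction. Signal over background is unknown, which limits the dim genes.

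Counts moved as follows. With the missing directions as covariates, which takes away 4 residual degrees of freedom, 850 genes were called at 6 h, 1694 at 24 h, 232 in the interaction and 427 at both times. An adjusted p under 0.01 left 853, 1637, 299 and 413, and a change of at least 1.5-fold 253, 313, 158 and 143, with 2762 for ethanol across the times. Tests per probe, over more features, gave 2836, 5726 and 1675 and, for ethanol, 35860. Array weights gave 1079 at 6 h and 5552 at 24 h, and the 6 h arrays alone 908. For ethanol, quantile normalization gave 5748, median centring 6394, normexp 8561 and leaving out genes below the median intensity 7633.

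The replicate numbers were not taken to pair the arrays. Over all genes, deviations of same-numbered arrays correlated at 0.256, 0.151, -0.0797 and 0.0548 at 6 h and at -0.928, -0.756, -0.729, -0.328 and -0.190 at 24 h. Among genes with a mean log2 value above 8, which were looked at first, the 6 h values were 0.511, 0.452, 0.143 and 0.262, so the outcome at 6 h depends on this filter. At 6 h, 3 of 8 arrays correlated best with their own number, and none at 24 h. The 24 h values cannot speak against a pairing, because the missing directions there lay along the numbers by 94.7%. Values that lack what same-numbered arrays share give negative correlations between them. The missing direction at 6 h, by 97.3% along the numbers, can lower the 6 h values too. With the number as a block 1220 genes were called at 6 h, 2255 at 24 h, 532 in the interaction, 14545 for ethanol and 560 at both times. With the block the adipocyte-like list was called in the interaction (0.0354) and the sarcomere list for ethanol (0.0385), and the calls of Rps7, Rpl19 and Atg5 were lost. It changed no other list or named gene.

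Camera's adjusted p with an estimated correlation was 0.0641 for inflammatory genes and 0.712 for oxidative phosphorylation at 6 h, and 0.0790, 0.133 and 0.721 for inflammatory, amino acid response and ribosomal genes at 24 h. In the interaction it was 0.442 for glycolysis and for oxidative phosphorylation, 0.282 for cholesterol synthesis, 0.547 for collagens, 0.433 for the amino acid response and 0.588 for ribosomal genes. For ethanol it was 0.243 for autophagy and inflammatory genes, 0.390 for cholesterol synthesis, collagens and the cell cycle, 0.568 for the amino acid response and 0.304 for ribosomal genes.

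Camera's adjusted p at the preset correlation crossed the threshold as follows. Ribosomal genes at 24 h had 0.0790 with quantile normalization, 0.0632 with the mean of a gene's probes, 0.0574 with array weights, 0.0505 with the missing directions and 0.0594 with normexp. Insulin genes at 6 h had 0.0926 without genes below the median intensity and 0.0911 with the mean of probes, oxidative phosphorylation at 6 h 0.0934 without those genes and 0.0528 with normexp, and inflammatory genes at 6 h 0.103 with the mean of probes. Glycolysis at 24 h gained a call with array weights (0.0471). In the interaction, ribosomal genes had 0.0505 with quantile normalization, 0.0669 with the mean of probes and 0.0524 with array weights. Collagens there had 0.255 with the mean of probes and 0.0840 with array weights, glycolysis 0.0932 with the mean of probes and 0.0551 without both arrays numbered 1, and the adipocyte-like list gained a call with quantile normalization (0.0494) and the missing directions (0.0404).

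For ethanol across the times, quantile normalization gave 0.158 for autophagy, 0.251 for inflammatory and for amino acid response genes and 0.0164 for sarcomere genes, and median centring 0.179 for inflammatory, 0.309 for amino acid response and 0.0121 for sarcomere genes. Without genes below the median intensity it was 0.329 for autophagy and the cell cycle, 0.279 for cholesterol synthesis and 0.237 for collagens, and without those below the lower quartile 0.0548 for autophagy and 0.0576 for the cell cycle. The mean of probes gave 0.0674 for autophagy and inflammatory genes and 0.189 for the cell cycle. Normexp gave 0.114 for inflammatory and 0.229 for amino acid response genes, and calls for proteasome (0.0178), sarcomere (0.00192), clock (0.0492) and oxidative phosphorylation genes (0.00367). Without both arrays numbered 1 the amino acid response had 0.217.

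With single arrays left out, camera's adjusted p ranged from 0.0162 to 0.0514 for insulin genes and from 0.00901 to 0.437 for oxidative phosphorylation at 6 h. At 24 h it ranged from 0.0171 to 0.241 for glycolysis, 0.0382 to 0.324 for oxidative phosphorylation, 0.0196 to 0.0873 for ribosomal genes and 0.0382 to 0.151 for the adipocyte-like list, and without ethanol replicate 5 the glycolysis, oxidative phosphorylation and adipocyte-like lists were called, glycolysis also without Dex replicate 5. In the interaction the ranges were 0.00203 to 0.0538 for glycolysis, 0.00335 to 0.340 for collagens, 0.00837 to 0.179 for ribosomal genes and 0.0376 to 0.145 for the adipocyte-like list. This list was called without ethanol replicate 4 or Dex replicate 3 at 6 h or ethanol replicate 1, 2 or 5 at 24 h. The calls of collagens were lost without ethanol 2 and 4 and Dex 1 at 6 h and ethanol 4 and Dex 2 and 5 at 24 h, and those of ribosomal genes without ethanol 2 and Dex 1 and 3 at 6 h and the same 3 arrays at 24 h. For ethanol they were 0.0169 to 0.104 for inflammatory, 0.0452 to 0.263 for sarcomere, 0.0141 to 0.0659 for cell cycle and 0.000467 to 0.134 for amino acid response genes. The calls ended without ethanol replicate 4 at 6 h (inflammatory), ethanol replicate 2 at 6 h (cell cycle) and ethanol replicate 1 at 24 h (amino acid response), and sarcomere genes were called without ethanol replicate 5 at 24 h. Among named genes, single arrays ended calls of Rps7, Rps3, Tyms and Sdhd at 6 h, of Rps19, Rps6 and Rpl19 at 24 h, and of Fgf21 and Ntn5 in the interaction, 38 of 1332 values in all.

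The mean of a gene's probes moved the log2 fold change of these called genes by over 1.5 times, with the sign kept. At 6 h it gave 0.45 for Usp2, 0.42 for Adamts1, 0.27 for Cblb, 0.21 for Mtor, 0.25 for Pik3r1, -0.39 for Irf1, -0.47 for Angptl4, -0.50 for Insig1, -0.28 for Vcam1, -0.79 for Timp3 and -0.70 for Cxcl12, and for Tyms -0.11, no longer called. At 24 h it gave 1.14 for Amy2a5, 0.87 for Per1, 0.65 for Vldlr, 0.50 for Usp2, 0.43 for Mybpc1, 0.29 for Pik3r1, 0.29 for Bcat2, -0.27 for Pfkp, -0.38 for Vcam1, -0.64 for Angptl4, -0.80 for Cxcl12, -1.15 for Trib3 and -0.99 for Spon2. For Cdk1 (0.07), Rps19 (0.13), Atg5 (-0.07) and Mcm6 (-0.11) the call at 24 h was lost with it. In the interaction it gave 0.64 for Amy2a5 and -0.81 for Rdh5, and for ethanol 0.17 for Eif4b, 0.28 for Magea2, 0.40 for Magea8, -0.74 for Lig1 and -1.40 for Itga11.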

Other observations

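Single genes differed in how their Dex effects went with time. The Notch target Hes1 was lower with Dex at both times (log2 fold change -0.69 at 6 h and -0.56 at 24 h), while Hey1 was lower at 6 h (-0.44) and higher at 24 h (0.38), with a difference of 0.81 (limma adjusted p = 0.000238), and Heyl, outside the lists, went from -0.24 to 0.42 (difference 0.67, adjusted p = 0.000111), although its fall at 6 h was not called with the missing directions as covariates (adjusted p = 0.106). Id2, an inhibitor of myogenic factors, was lower at both times (-0.84 and -0.66). Omd, an osteoblast-like marker, rose at 6 h by 1.32 and had a difference of -1.03 at 24 h. These genes were chosen after their values were seen.

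Serpina3n, Orm1, Saa3 and Lbp, all acute-phase genes, were among the named genes. The hypothesis that acute-phase genes rise as a class was tested on 21 other measured members of a list of 24, written after these 4 were seen and before the test. Of these, 3 rose and none fell at 24 h. Camera of limma gave an unadjusted p of 0.0792 (0.0751 with an estimated correlation), so a rise of the class was not shown. The members that rose were Il1rn (0.96), Hp (0.77) and Cp (0.72). At 6 h, 2 of the 21 rose.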
